A study of Mus musculus with 6 samples.

How the data were processed

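RNA from 6 immortalized mouse embryonic fibroblast clones, 3 FHL2 knockout (clones E, H and J) and 3 wild type (clones E, F and I), had been labelled with biotin by a single-cycle 3' protocol and hybridised to 1-colour Affymetrix arrays of 45101 probe sets, 1 array per clone. The deposited values were log2 intensities that the authors had made with RMA, which is named in the submitters' processing notes and corrects background, normalizes by quantiles and summarizes probes. The version and the settings of RMA are not given in the sources used here. The values of wild type clone E are written with 9 decimals and those of the other clones with 3, so that array may have been processed separately; whether it was is not given in the sources used here. Arrays have no read depth, and the number of clones per genotype sets the precision: 3 and 3 clones leave 4 residual degrees of freedom.

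Groups and clone letters were taken from the sample titles. The 64 control probe sets were left out. So were 932 probe sets with several gene symbols and 9160 without a gene name, which were read from a second fit over all 45037 other probe sets. The remaining 34945 probe sets carried 1 symbol, of which 34741 were found by gene ID in the RefSeq table of assembly GRCm38.p6; 0 symbols changed. That table was used for names and for the order of neighbouring genes alone. Each of the 18193 genes was represented by its probe set with the highest mean over the 6 arrays, a rule that does not use the genotype; 9010 genes had more than 1 probe set. In 29 genes probe sets passed in opposite directions, and 0 of these genes are named. No gene was left out of the main comparison for a low level.

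Knockout and wild type clones were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior, genotype alone), with p-values adjusted by Benjamini-Hochberg at 0.05. Fhl2 was also given an exact two-sided permutation test. Before the data were examined, 30 gene lists were fixed and tested with camera at the preset correlation of 0.01 between genes, adjusted over lists; camera sets a list against all other genes. Members were counted after adjustment over all genes and over the list alone. Principal components and Pearson correlations over genes were computed without a test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

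The genes to be named were also fixed by rule before the data were examined. They were Fhl2, the 15 largest rises and 15 largest falls among genes that passed, had groups without overlap and had a higher group mean at or above the median of gene means (5.92), up to 4 members of each list with the smallest unadjusted p, and the D cyclins, Cdkn1a, Cdkn2a, Cdkn2b, Mki67, Fhl1 and Fhl3. This gave 142 genes. Xist and Y-linked transcripts were read per clone as description. Some genes that the rule or the lists name were not analysed here. Genes singled out later are said to be so.

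Alternatives fixed before the data were examined were a trended robust prior, quantile normalization again, median centring of arrays, only genes at or above the median mean level, the mean of a gene's probe sets, every probe set tested, probe sets open to cross-hybridization (_x_at, _s_at and _a_at) left out, array weights, a 2-fold threshold, each clone left out, estimated correlations in camera, the test fry, and components over the 1000 most variable genes. Added afterwards were leaving out genes of the X and Y chromosomes and subtracting the median of the 40 nearest measured genes on the chromosome from each gene in each clone. Later tests used all 10 splits of the 6 clones into 3 and 3, windows of 40 genes at steps of 20 with a threshold of 0.4 and 100 shuffled gene orders, the 10 measured genes on each side of the Hoxc cluster, and 10000 random lists matched on size and level for 4 further lists: second p53 targets, positional transcription factors, the insulin-like growth factor axis and MHC class I antigen presentation.

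The pipeline was tested on simulated data of 18193 genes with 200 genes changed. It recovered 66% of 2-fold and 89% of 4-fold changes, and 3.12% of its calls were false (5 unchanged genes). Camera called 1 list with none changed and 2 with the mitosis list shifted. The window method found 0 windows without a regional shift and 10 of 10 with 1 chromosome lowered in 1 clone. There it gave a median of -0.98 for a set value of -1. Noise in the simulation was drawn independently for each gene. In the measured clones genes of a list moved together, with an estimated correlation of 0.74 for the mitosis list. The recovery rates, false calls and window counts of the simulation therefore need not hold for the measured clones.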

Results

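Gene expression was measured on 6 arrays, each hybridised with RNA from a separate clone of mouse embryonic fibroblasts that had become immortal in culture without an introduced oncogene. The 2 groups held 3 clones each: clones E, H and J were FHL2 knockout, and clones E, F and I were wild type. FHL2 is an adaptor protein made of LIM zinc-finger domains that binds transcription factors, among them AP-1 and beta-catenin, and the cytoplasmic tails of integrins. The comparison asks which transcripts differ between fibroblasts with and without this adaptor. On the log2 scale, array medians were 4.51 to 4.54 in knockout and 4.44 to 4.46 in wild type clones, so they moved with genotype, and 18193 genes were tested. The 3' to 5' difference of Gapdh also lay apart by genotype (-0.119 to -0.045 in knockout and -0.041 to 0.052 in wild type clones), while that of actin overlapped (0.103 to 0.235 and 0.093 to 0.133). Differences are given as knockout minus wild type on the log2 scale with the standard error (SE) of the limma fit, n = 3 clones per genotype, and genes are said to rise, fall or change where the adjusted p lay under 0.05. The number of arrays limits the precision, with a median SE of 0.141 over all genes. The labels do not say whether the clones of a genotype came from separate embryos, so the p-values measure the spread between clones. For gene lists, square brackets give the range of the median over the 15 alternative settings with the preset correlation, the fits that leave out 1 clone among them.

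Fhl2 itself was read by 1 probe set and was lower in all 3 knockout clones. Its level was 6.01, 6.44 and 6.57 in knockout clones E, H and J, against 9.88, 8.57 and 9.64 in wild type clones E, F and I. The group means were 6.34 ± 0.289 (SD, n = 3) and 9.36 ± 0.699 (SD, n = 3), so Fhl2 fell by 3.02 on the log2 scale (SE 0.35, limma adjusted p = 0.00400), or 8.13-fold. The knockout mean lay at percentile 54.4 of the knockout means of all genes, so a reading in the middle of the scale remained. An exact two-sided permutation test of the group means gave p = 0.10, the smallest value that the 20 assignments of 3 clones against 3 allow. Whether this probe set lies in the deleted part of the gene is not given in the sources used here; a probe set outside that part would not check the labels.

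The clones separated by genotype along the first principal component, which held 67.5% of the variance over genes. Wild type clones lay close together, with pairwise correlations across genes of 0.988 to 0.991, as did knockout clones E and J at 0.991. Knockout clone H stood apart from its group, at 0.964 with clone E and 0.968 with clone J, and accounted for most of the second component (18.6% of the variance; -57.0 for clone H against 25.3 and 16.7 for clones E and J). Correlations between genotypes ran from 0.934 to 0.953; genes are not independent replicates in these values. Xist, the RNA that silences one X chromosome in female cells, was read at 9.82 in knockout clone H and at 4.69 to 5.11 in the other clones. The Y-linked gene Eif2s3y was read at 2.92 in clone H and at 7.47 to 8.79 elsewhere, Kdm5d at 2.34 against 6.50 to 7.72, and Uty at 3.96 against 5.40 to 6.38. Of the 591 genes whose SD among knockout clones exceeded 1, clone H lay farthest from the others in 83.2%, while 103 genes had such an SD among wild type clones.

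**Figure D1:**
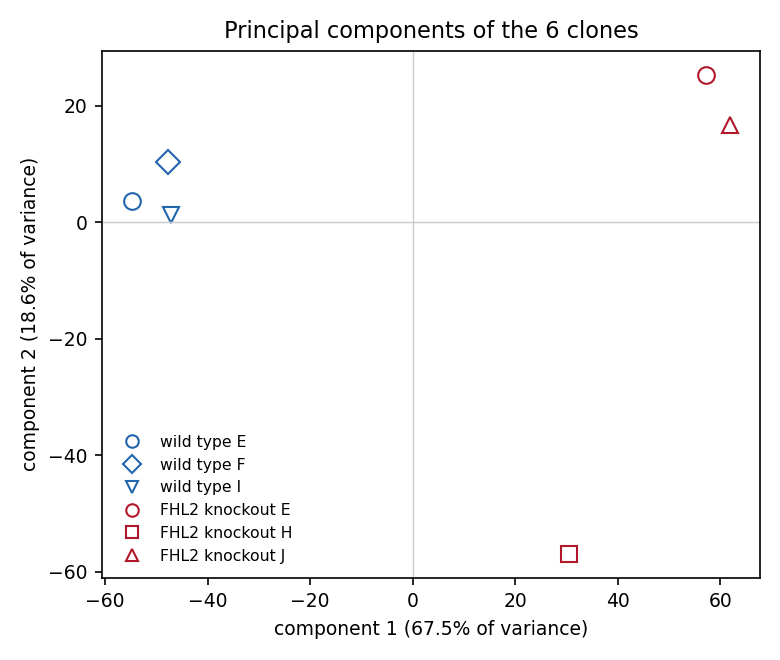
Positions of the 6 clones on the first and second principal components over 18193 genes, which hold 67.5% and 18.6% of the variance. The knockout clones lie on one side of the first component and the wild type clones on the other, and knockout clone H lies apart from the rest on the second.

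Loss of FHL2 went with a difference in 3464 genes, of which 1644 were higher and 1820 lower in knockout clones. The largest measured rise was that of Scara5, a scavenger receptor that takes up ferritin (7.84, SE 0.43, adjusted p = 5.47e-04), which moved to 4.12 when all probe sets of the gene were averaged. Pcdh19, a protocadherin of cell adhesion, rose by 6.66 (SE 0.46), Fbn2, a fibrillin of elastic microfibrils, by 6.55 (SE 0.54), and Agtr2, an angiotensin receptor, by 6.47 (SE 0.72). Egfl6, a secreted matrix protein, rose by 6.17 (SE 0.65), Ahr, the aryl hydrocarbon receptor, by 5.79 (SE 0.60), and Tox, a DNA-binding protein with an HMG box, by 5.45 (SE 0.35). Wild type readings of Scara5 (3.67), Pcdh19 (3.71), Egfl6 (2.53), Tmem178 (2.91), Tox (3.29) and Ahr (3.30) lay near the lower end of the scale. So did those of Lgr5 (3.47), Tmem26 (3.69) and Olfml1 (3.83), and the sizes and order of these rises are not exact. Tmem178, Olfml1 and Tmem26 rose by 5.2, 5.13 and 4.92. AW551984 and Igdcc4 rose by 5.73 and 4.94, or by 2.38 and 2.63 with probe sets averaged. Sfrp2, a secreted modulator of Wnt signalling, rose by 6.38 (SE 1.33, adjusted p = 0.0219), Lgr5, a receptor for R-spondins, by 5.78 (SE 1.20, adjusted p = 0.0215), and Matn4, a matrilin, by 5.17 (SE 0.98, adjusted p = 0.0164). These 3 genes were less raised in clone H, at 8.84, 6.31 and 7.72, than in clones E and J. The call of Sfrp2 was lost without knockout clone E (adjusted p = 0.0675), knockout clone J (0.0755), wild type clone E (0.0814) or wild type clone I (0.0674). That of Lgr5 was lost without any clone other than knockout clone H (0.0520 to 0.0815), and its value was 3.13 with probe sets averaged. That of Matn4 was lost without knockout clone J (0.0624), wild type clone E (0.0694), wild type clone F (0.0514) or wild type clone I (0.0544).

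The largest measured fall was that of Hoxc8, a homeobox gene of body position, from 10.2 ± 0.0885 (SD, n = 3) in wild type to 2.99 ± 0.151 (SD, n = 3) in knockout clones, a measured fall of 152-fold (-7.25, SE 0.12, adjusted p = 5.86e-06). Hoxc4 and Hoxc6 of the same cluster fell by 5.15 (SE 0.16) and 4.51 (SE 0.21). Ctla2a and Ctla2b, which encode related inhibitors of cysteine proteases, fell by 7.16 (SE 0.58) and 5.78 (SE 0.19). Sprr1a, a protein of the cornified envelope, fell by 6.24 (SE 0.16), and Efemp1, a fibulin of the extracellular matrix, by 5.56 (SE 0.40). Tac1, the precursor of substance P, fell by 5.35 (SE 0.53), Cxcl10, a chemokine induced by interferon, by 5.14 (SE 0.40), and Prkg2, a kinase activated by cyclic GMP, by 4.89 (SE 0.17). 3110039M20Rik fell by 4.72 (SE 0.22) and Gpnmb, a transmembrane glycoprotein, by 4.51 (SE 0.15). With probe sets averaged, Tac1 and Gpnmb moved to -2.74 and -2.92. Knockout readings of Hoxc8 and of others, such as Ctla2b (2.42), Hoxc4 (3.39) and Tac1 (3.74), lay near the lower end of the scale. The sizes and order of these falls are therefore not exact. Actg2, an actin of smooth muscle, fell by 4.64 (SE 1.09, adjusted p = 0.0311), a call lost without knockout clone E (0.0889), knockout clone J (0.102), wild type clone E (0.0939) or wild type clone F (0.0941). Rnf128, a ubiquitin ligase, fell by 4.87 and Clca3a1 by 4.64, and both calls were lost without wild type clone E (adjusted p = 0.0567 and 0.0507).

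Genes that passed made up 19% of those tested, and 1495 of them differed by at least 2-fold. At an unadjusted p under 0.05 there were 6037. In 7073 genes, or 38.9%, the values of the genotypes did not overlap, where chance gives 10%. The count depended on the clones: it was 2079 without knockout clone E, 1733 without knockout clone J, 1661 without wild type clone E, 1910 without wild type clone F and 2145 without wild type clone I, and 4750 without knockout clone H. Of the 118 named genes that passed, 77 passed in each of the 6 fits that leave out 1 clone.

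Most genes of the G1/S transition lay lower in knockout clones (22 of 24 below 0), though fewer passed singly. Of the 24 measured D cyclins and G1/S regulators, 8 fell, 1 rose and 15 did not pass (15 lower and 1 higher when adjusted over the list alone). The gene that rose was Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, by 3.70 (SE 0.27, adjusted p = 0.00131), from 7.01 ± 0.335 to 10.7 ± 0.463 (SD, n = 3). Among those that fell were Ccnd2, a D cyclin, by 1.26 (SE 0.18, adjusted p = 0.00703), its partner kinase Cdk6 by 1.48 (SE 0.21, adjusted p = 0.00673) and Cdkn2a, the locus of the p16 and Arf proteins, by 2.0 (SE 0.30, adjusted p = 0.00827). Ccnd1, the cyclin D1 gene, fell by 1.70 (SE 0.33, adjusted p = 0.0177), a call lost without wild type clone E (0.0731) or wild type clone F (0.0605). Ccnd3 differed by -0.64 (SE 0.21, adjusted p = 0.0858) and passed without wild type clone I (-0.84, 0.0387); with probe sets averaged it was -0.28. Cdkn2b, the p15 inhibitor, differed by -0.99 (SE 0.35, adjusted p = 0.0994) and passed without knockout clone H (-1.33, 0.0126) and with array weights (-1.24, 0.0236). The list as a whole lay lower than other genes (median -0.66, camera adjusted p = 7.29e-05; adjusted p = 0.326 with an estimated correlation).

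Most DNA replication and mitosis genes also lay lower (19 of 21 and 23 of 24 below 0). Of 21 measured replication genes, 7 fell and 0 rose (12 lower when adjusted over the list alone; median -0.61, or -0.41 without wild type clone E; camera adjusted p = 4.80e-06; adjusted p = 0.582 with an estimated correlation). Gins2, a subunit of the replicative helicase, fell by 1.14 (SE 0.20, adjusted p = 0.0126). Cdc45, another helicase component, fell by 1.28 (SE 0.13), and the licensing factor Cdt1 by 1.26 (SE 0.16), or by 0.56 and 0.81 with probe sets averaged. Rfc4, of the clamp loader, fell by 0.95 (SE 0.16, adjusted p = 0.0114), a call lost without wild type clone E (0.0511). Of 24 measured mitosis genes, 14 fell and 0 rose (17 lower when adjusted over the list alone; median -0.91, camera adjusted p = 9.89e-09; adjusted p = 0.582 with an estimated correlation). The checkpoint kinase Bub1 fell by 1.65 (SE 0.27) and the kinetochore motor Cenpe by 1.08 (SE 0.17). Foxm1, a transcription factor of the G2/M programme, fell by 1.67 (SE 0.22), or by 0.92 with probe sets averaged. Cenpa, the centromeric histone, fell by 1.63 (SE 0.22, adjusted p = 0.00587), but did not pass without probe sets open to cross-hybridization (-0.59, adjusted p = 0.426) or with probe sets averaged (-0.78, adjusted p = 0.0568). The proliferation marker Mki67 differed by -0.49 (SE 0.24), which did not pass (adjusted p = 0.209), and by -0.32 without wild type clone E.

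Of the targets of p53, 14 lay above 0 and 5 below in knockout clones. Of 19 measured members, 10 rose, 1 fell and 8 did not pass, with the same counts when adjusted over the list alone (median 0.70, or 1.19 over the more highly expressed genes alone; camera adjusted p = 3.16e-04; adjusted p = 0.326 with an estimated correlation). Besides Cdkn1a, Trp53inp1, a stress-induced protein that acts with p53, rose by 3.06 (SE 0.15, adjusted p = 3.76e-04) and lay between 9.53 and 9.62 in the knockout clones against 6.31 to 6.81 in the wild type clones. Zmat3, an RNA-binding protein, rose by 2.41 (SE 0.14, adjusted p = 6.02e-04) and Ccng1, cyclin G1, by 1.65 (SE 0.15, adjusted p = 0.00214). The member that fell, Gadd45a, a stress-response gene, differed by -2.97 (adjusted p = 0.0125); it was singled out after its values were seen. In knockout clone H, Cdkn1a read 11.2 and Foxm1 6.70, against 6.65 to 7.31 and 8.11 to 8.93 in wild type clones.

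**Figure D2:**
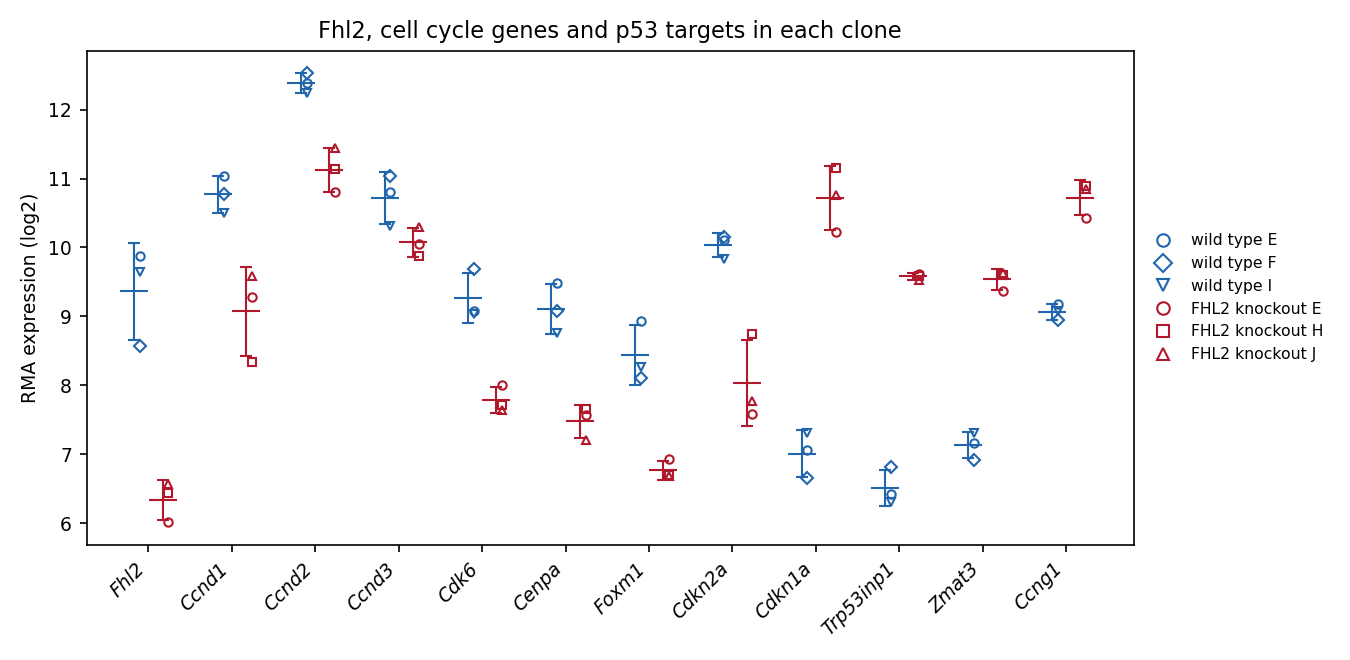
Log2 expression of Fhl2, cell cycle genes and p53 targets in each of the 3 knockout and 3 wild type clones, with the mean and SD of each genotype. Cdkn1a, Trp53inp1, Zmat3 and Ccng1 lie higher in every knockout clone than in any wild type clone, and Ccnd2, Cdk6, Cdkn2a and Foxm1 lie lower.

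Interferon-stimulated genes showed the largest shift of any list. Of 23 measured members, 13 fell, 2 rose and 8 did not pass (18 lower and 2 higher when adjusted over the list alone; median -2.49, camera adjusted p = 6.56e-10; adjusted p = 0.582 with an estimated correlation). Usp18, a protease that removes ISG15 from proteins, fell by 4.0 (SE 0.29, adjusted p = 0.00130), Ifih1, the RNA sensor MDA5, by 3.35 (SE 0.22, adjusted p = 9.47e-04) and Oasl1, of the oligoadenylate synthetase family, by 2.86 (SE 0.20, adjusted p = 0.00117). The 2 that rose, named after their values were seen, were Psmb9, an immunoproteasome subunit, by 0.64 and Irf1, an interferon-regulated transcription factor, by 0.47. The call of Psmb9 was lost without knockout clone J (adjusted p = 0.0608) or wild type clone E (0.0544), and that of Irf1 without any clone other than knockout clone H (0.0581 to 0.0943) or after the median of neighbouring genes was subtracted (0.114).

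Among 22 chemokines and NF-kB targets, 3 fell and 2 rose (the same when adjusted over the list alone), and the list did not pass (median -0.24 [-0.66 to -0.15 over settings], camera adjusted p = 0.264). Besides Cxcl10, the chemokine Ccl5 fell by 2.86 (SE 0.46, adjusted p = 0.00986) and Ccl2 by 2.21 (SE 0.37, adjusted p = 0.0109), the latter lost without wild type clone E (0.0507). Cxcl1, a chemokine for neutrophils, rose by 2.25 (SE 0.21, adjusted p = 0.00233), or by 4.82 without probe sets open to cross-hybridization. The 19 senescence-associated secreted factors held 2 rises and 4 falls under either adjustment (median -0.15 [-0.78 to 3.4e-04 over settings], camera adjusted p = 0.395). Igfbp4, a binding protein of insulin-like growth factors, rose by 2.54 (SE 0.33), while the matrix protease Mmp3 fell by 4.43 (SE 0.53) and Igfbp7 by 1.70 (SE 0.27), or by 1.09 with probe sets averaged for Igfbp7.

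Collagens and other matrix genes lay more often above 0 than below in knockout clones (25 and 7). Of 32 measured members, 10 rose, 1 fell and 21 did not pass, with the same counts when adjusted over the list alone (median 0.30, camera adjusted p = 0.00548; adjusted p = 0.587 with an estimated correlation). After Fbn2, the largest rise among the named members was that of elastin, Eln, by 3.60 (SE 0.50, adjusted p = 0.00654), and the collagen VI chains Col6a2 and Col6a1 rose by 1.30 (SE 0.10, adjusted p = 0.00162) and 0.85 (SE 0.10, adjusted p = 0.00391). The fall was that of Thbs2, a thrombospondin, named after its values were seen (-3.12, adjusted p = 0.0279), and was lost without knockout clone J (0.0896), wild type clone E (0.0844), wild type clone F (0.0922) or wild type clone I (0.0765). The list did not pass without knockout clone H (median 0.18, adjusted p = 0.0829), and its median was 0.46 without knockout clone E, 0.19 with array weights and 0.48 with probe sets averaged. Matrix proteases and their inhibitors did not move together: of 20 members, 2 rose and 1 fell under either adjustment (median -0.18 [-0.38 to -0.01 over settings], camera adjusted p = 0.565). Besides Mmp3, the gelatinase Mmp9 rose by 0.83 (SE 0.14, adjusted p = 0.0122), or by 1.36 with probe sets averaged.

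Of 24 TGF-beta and BMP signalling genes, 4 rose and 2 fell (6 and 2 when adjusted over the list alone; median 0.37, camera adjusted p = 0.271). Ltbp2, a matrix protein related to latent TGF-beta binding proteins, rose by 3.66 (SE 0.39, adjusted p = 0.00323), and the receptor Tgfbr2 by 1.75 (SE 0.25, adjusted p = 0.00687). Nog, the BMP antagonist noggin, rose by 1.39 (SE 0.25, adjusted p = 0.0131), a call lost without wild type clone E (0.0578) or wild type clone F (0.0519). Smad7, an inhibitor of TGF-beta signalling, fell by 0.76 (SE 0.16, adjusted p = 0.0203), a call lost without knockout clone E (0.0666), wild type clone E (0.0768) or wild type clone F (0.0711).

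Integrin and focal adhesion genes lay lower as a list, though few passed singly. Of 24 members, 3 fell, 2 rose and 19 did not pass, with the same counts when adjusted over the list alone (median -0.37, camera adjusted p = 0.0129; adjusted p = 0.582 with an estimated correlation). Bcar1, the p130Cas scaffold, fell by 1.25 (SE 0.16, adjusted p = 0.00476). Itgb3, an integrin chain, rose by 1.18 (SE 0.18, adjusted p = 0.00885), or by 0.75 after the median of neighbouring genes was subtracted. Cav1, the caveolin of membrane pits, rose by 1.07 (SE 0.24, adjusted p = 0.0289), a call lost without knockout clone J (0.0800), wild type clone F (0.0828) or wild type clone I (0.0857). The list did not pass without knockout clone E (adjusted p = 0.0738), without wild type clone E (0.0615) or over the more highly expressed genes alone (0.227), and its median was -0.57 without knockout clone H.

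Cytoskeletal targets of SRF and MRTF passed as a list by a narrow margin. Of 26 members, 3 fell, 1 rose and 22 did not pass under either adjustment (median -0.27, camera adjusted p = 0.0478; adjusted p = 0.707 with an estimated correlation). The call held in 5 of 15 alternative settings, where its adjusted p ran from 5.43e-05 to 0.256, and was lost without knockout clone E (0.153), knockout clone J (0.166), wild type clone E (0.234) or wild type clone I (0.0726). Its median was -0.67 without knockout clone H, -0.48 with array weights, -0.45 after regional subtraction and -0.41 over the more highly expressed genes. Myh9, the heavy chain of nonmuscle myosin, fell by 0.94 (SE 0.16, adjusted p = 0.0108). Egr2, an early-response transcription factor, rose by 2.39 (SE 0.47, adjusted p = 0.0186), a call lost without knockout clone E (0.0611), knockout clone J (0.0636), wild type clone E (0.0772) or wild type clone F (0.0657).

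The 16 YAP/TEAD targets held 1 rise and 2 falls (1 and 3 when adjusted over the list alone), and the list did not pass (median -0.20 [-0.28 to -0.13 over settings], camera adjusted p = 0.318) except without knockout clone H (0.0389). Ankrd1, a muscle ankyrin repeat protein, fell by 2.40 (SE 0.41, adjusted p = 0.0113), a call lost without wild type clone E (0.0509). Among 29 LIM-domain proteins other than FHL2, 3 rose and 2 fell under either adjustment (median -0.16 [-0.66 to -0.11 over settings], camera adjusted p = 0.349), and the list passed without knockout clone H (0.0158). Csrp2, a cysteine-rich LIM protein, rose by 1.8 (SE 0.23, adjusted p = 0.00522). Of the relatives of Fhl2, Fhl1 read 6.33, 10.7 and 7.93 in knockout clones E, H and J against 10.9 to 11.7 in wild type clones (-2.87, SE 1.02), which did not pass (adjusted p = 0.103). It passed without knockout clone H (-4.06, adjusted p = 0.00210) and with array weights (-3.54, adjusted p = 0.0158), and its difference was -1.88 without knockout clone E and -1.41 with probe sets averaged. Fhl3 rose by 0.42 (SE 0.10, adjusted p = 0.0282), a call lost without knockout clone J (0.0950), without wild type clone E (0.0863), wild type clone F (0.0769) or wild type clone I (0.0835), and after quantile normalization (0.0513) or median centring of the arrays (0.0543).

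**Figure D3:**
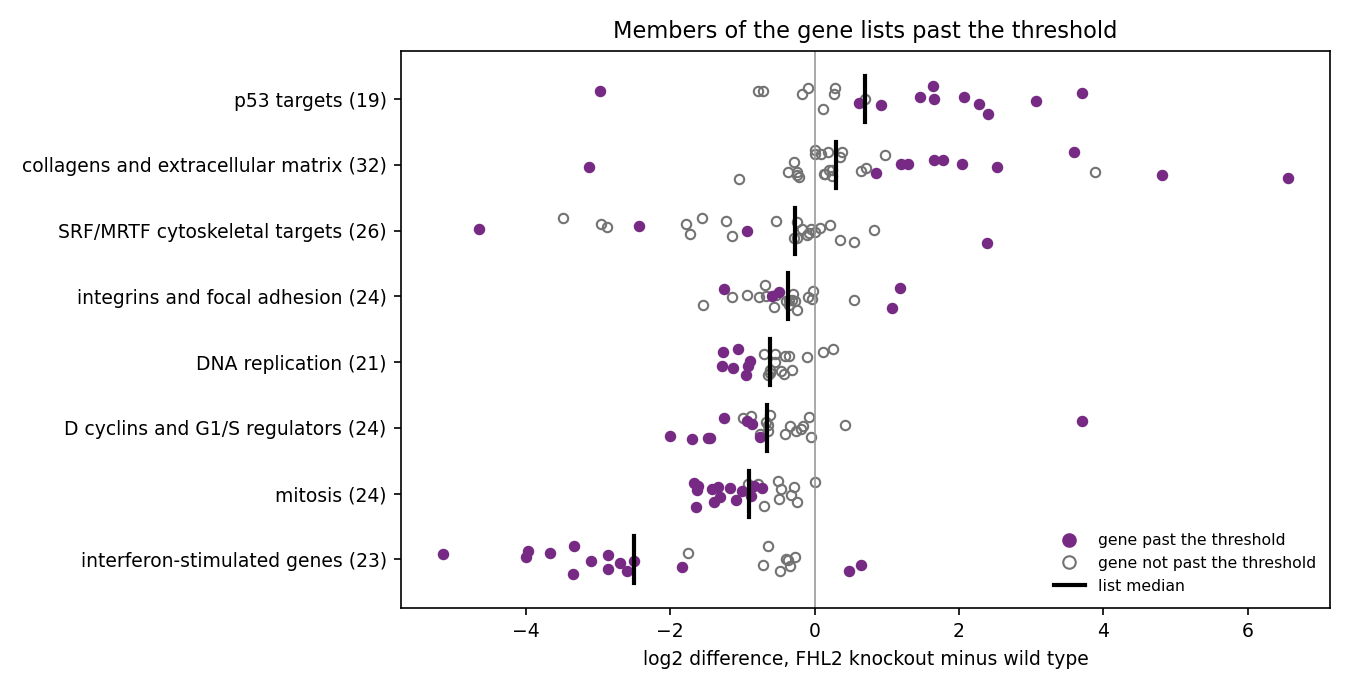
Log2 difference, knockout minus wild type, of each measured member of the 8 gene lists that passed camera; filled points passed the adjusted p of the gene test and the bar marks the list median. The medians run from -2.49 for interferon-stimulated genes to 0.70 for p53 targets.

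In all, 8 of the 30 lists passed with the preset correlation between genes, 2 upward and 6 downward, and 0 passed with estimated correlations, where the smallest adjusted p was 0.326. Other splits of the 6 clones into 3 and 3 called up to 10 lists. Without knockout clone H, 14 lists passed. Of 586 distinct list members measured, 163 changed, or 27.8%; this was 253 without knockout clone H, 100 without knockout clone J and 90 without wild type clone E; the other fits that leave out 1 clone gave 112 to 132. The test fry asks whether the genes of a list move, on balance, one way, without setting them against other genes. It passed 7 lists: G1/S regulators (adjusted p = 0.00904), p53 targets (8.09e-04), interferon-stimulated genes (0.0128), collagens and matrix (0.0343), Hox genes (8.09e-04), NRF2 targets (0.0163) and bone and cartilage markers (0.0219). The direction was up for p53 targets, collagens and matrix, and bone and cartilage markers, and down for the other 4. Among the Hox genes 21 of 33 nevertheless lay above 0 (median 0.08). DNA replication and mitosis genes both missed (0.0615), as did integrins (0.106) and SRF/MRTF targets (0.331). For changes in either direction, fry passed all 30 lists, among them macrophage markers and bone and cartilage markers, of which 0 genes passed singly. With 19% of all genes tested past the threshold, this result does not set any list apart.

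The Hox genes, which specify position along the body axis, held changes in both directions, though most members did not pass. Of 33 measured members, 6 rose and 5 fell (7 each when adjusted over the list alone), and camera did not separate the list from other genes (adjusted p = 0.504; median 0.08 [-0.91 to 0.08 over settings], mean -0.59). The 5 falls after adjustment over all genes were in the Hoxc cluster: besides Hoxc8, Hoxc4 and Hoxc6, Hoxc5 fell by 3.82 (SE 0.19, adjusted p = 4.24e-04). Hoxc9, chosen after its values were seen, differed by -1.79 (SE 0.16, adjusted p = 0.00206), with readings of 6.37, 6.34 and 6.34 in the knockout clones against 7.90 to 8.48 in the wild type clones. The measured Hoxc10 and Hoxc13 did not pass (0.08 and 0.07). Their wild type means were low, at 2.72 and 3.93, which left little room for a fall. The rises, also picked out after the values were seen, were those of Hoxa2 (2.59), Hoxa3 (1.72), Hoxa7 (0.85), Hoxd1 (0.77), Hoxd3 (1.03) and Hoxd9 (2.10). The calls of Hoxa3, Hoxd3 and Hoxd9 were lost without any clone other than knockout clone H, at adjusted p = 0.0865 to 0.127, 0.0705 to 0.113 and 0.0641 to 0.101. That of Hoxd1 was lost without knockout clone J (0.0856), wild type clone E (0.123), wild type clone F (0.0858) or wild type clone I (0.106), and after median centring (0.0554) or regional subtraction (0.126). That of Hoxa3 was also lost after regional subtraction (0.0505) and without probe sets open to cross-hybridization (0.58, adjusted p = 0.070), and its value was 0.72 with probe sets averaged. Hoxb6 and Hoxb9, singled out for their spread, read 3.28 and 4.18 in knockout clone E and 3.24 and 4.65 in clone J, but 6.52 and 8.24 in clone H, within 1 log2 unit of some wild type clones. Neither passed over all genes (adjusted p = 0.0805 and 0.140), and both did without knockout clone H (1.17e-04 and 7.04e-04) and with array weights (0.00787 and 0.0160). Hoxb4 (-0.91) and Hoxb6 made up the other 2 falls when adjusted over the list alone (both 0.0495).

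**Figure D4:**
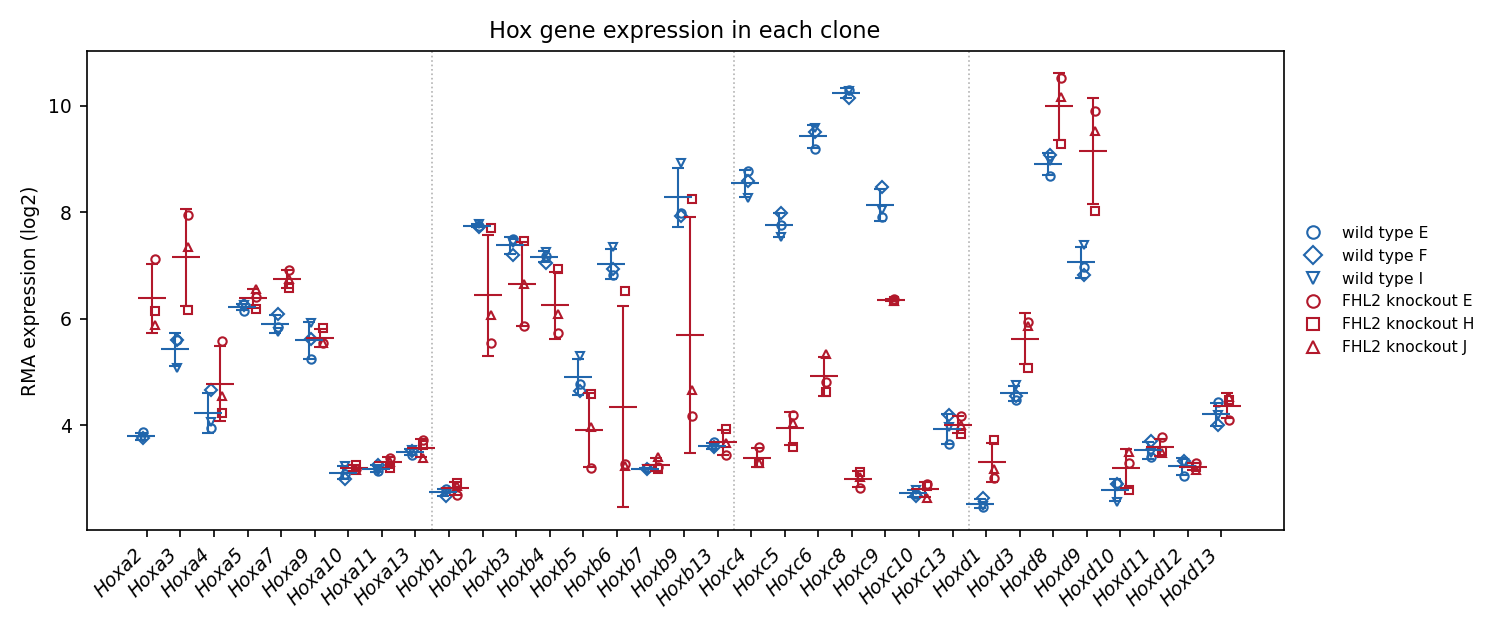
Log2 expression of the 33 measured Hox genes in each clone, arranged by cluster. Hoxc4, Hoxc5, Hoxc6, Hoxc8 and Hoxc9 lie lower in all 3 knockout clones, and Hoxb6 and Hoxb9 are low in knockout clones E and J but not in H.

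Genes tied to beta-catenin and AP-1, partners of FHL2, did not move as lists. Of 19 Wnt/beta-catenin targets, 4 rose and 3 fell (5 and 4 when adjusted over the list alone; camera adjusted p = 0.955); the list median was 0.05 [-0.20 to 0.18 over settings] and the mean 0.48, while camera placed the list below other genes. Besides Lgr5 and Ccnd1, the growth regulator Myc fell by 0.87 (SE 0.19, adjusted p = 0.0250), a call lost without knockout clone E (0.0705), knockout clone J (0.0669) or wild type clone E (0.0771). Of 18 AP-1 components and targets, 2 rose and 4 fell (5 and 6 when adjusted over the list alone; median -0.61 [-0.77 to -0.31 over settings], camera adjusted p = 0.230), and the list passed without knockout clone H (0.0389). Its median was -0.32 without knockout clone E and -0.31 without wild type clone I. Hbegf, a growth factor that binds the EGF receptor, fell by 2.40 (SE 0.26, adjusted p = 0.00344) and the AP-1 subunit Fosl1 by 1.61 (SE 0.24, adjusted p = 0.00760).

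None of the 4 metabolic and stress lists passed camera, and 3 of them held changes in both directions. Of 17 hypoxia and glycolysis genes, 5 fell and 0 rose under either adjustment (median -0.11 [-0.26 to 0.03 over settings], camera adjusted p = 0.209), and the list passed without knockout clone H (0.0339). Pfkp, a phosphofructokinase, fell by 1.65 (SE 0.26, adjusted p = 0.00907), or by 1.06 with probe sets averaged. Of 15 cholesterol synthesis genes, 2 rose and 2 fell under either adjustment (median -0.19 [-0.35 to -0.04 over settings], camera adjusted p = 0.401). Sc5d, a sterol desaturase, fell by 1.44 (SE 0.22, adjusted p = 0.00833), which did not pass with probe sets averaged (-0.55, adjusted p = 0.0978). Of 18 genes of the unfolded protein and amino acid stress responses, 3 rose and 4 fell (3 and 6 when adjusted over the list alone; median -0.36 [-0.52 to -0.10 over settings], camera adjusted p = 0.0827). That list passed without knockout clone H (0.0196), without wild type clone F (0.0341) and with array weights (0.0353). The endoplasmic reticulum chaperone partner Dnajb9 rose by 1.58 (SE 0.22), while Edem1, of misfolded protein disposal, fell by 1.19 (SE 0.13) and Phgdh, of serine synthesis, by 1.09 (SE 0.13). Of 15 NRF2 targets, 3 rose and 6 fell (4 and 7 when adjusted over the list alone; camera adjusted p = 0.209); the median was -0.23 [-0.50 to -0.12 over settings] and the mean 0.03, and camera placed the list below other genes. The quinone reductase Nqo1 rose by 2.42 (SE 0.28), while Txnrd1, a thioredoxin reductase, and Gclm, of glutathione synthesis, fell by 1.06 (SE 0.17) and 0.77 (SE 0.12).

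Among 18 imprinted genes, 5 rose and 1 fell (7 and 1 when adjusted over the list alone; median 0.47 [0.34 to 0.93 over settings]). Igf2, the fetal growth factor, rose by 4.81 (SE 0.22, adjusted p = 3.76e-04), to 13.4 ± 0.169 (SD, n = 3), and the proteolipid gene Nnat fell by 4.22 (SE 0.35, adjusted p = 0.00172). Mest rose by 3.01 (SE 0.56, adjusted p = 0.0155), a call lost without knockout clone J (0.0591) or wild type clone E (0.0595). Plagl1, a zinc-finger regulator of imprinted genes, rose by 2.25 (SE 0.43, adjusted p = 0.0163), a call lost without knockout clone E (0.0535) or knockout clone J (0.0625). The list did not pass (camera adjusted p = 0.0999), and it passed in 6 of 15 alternative settings, among them without knockout clone H (0.0140) and without wild type clone F (0.0169).

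No list of markers of cell types other than fibroblasts passed camera, and 1, that of bone and cartilage, passed fry. The 22 skeletal muscle markers held 0 rises and 2 falls under either adjustment (median 0.04 [-1.69 to 0.07 over settings], mean -0.18, direction down, camera adjusted p = 0.871): Tnnt2, a cardiac troponin, differed by -3.98 (SE 0.69, adjusted p = 0.0120) but by 0.29 (adjusted p = 0.216) without probe sets open to cross-hybridization, and Pax3 fell by 0.97 (SE 0.17). The 12 adipocyte markers held 1 rise and 2 falls (2 and 2 when adjusted over the list alone; median 0.11 [-0.02 to 0.23 over settings], camera adjusted p = 0.742), the rise being that of the transcription factor Cebpa, by 4.6 (SE 0.59, adjusted p = 0.00514). Of 17 bone and cartilage markers, 0 passed in limma under either adjustment and 15 lay above 0 (median 0.18 [0.10 to 1.43 over settings], camera adjusted p = 0.0925, fry adjusted p = 0.0219). The cartilage collagen Col2a1 differed by 3.21 (SE 1.11, unadjusted p = 0.0251, adjusted p = 0.0951), with 5.86 in knockout clone H against 10.6 and 9.15 in clones E and J. Without clone H, Col2a1 passed (4.54, adjusted p = 7.70e-04), as did the list (0.0324), and Col2a1 also passed with array weights (3.99, adjusted p = 0.0117). The 17 epithelial markers held 1 rise and 1 fall under either adjustment (median 0.01 [-0.06 to 0.28 over settings], mean -0.20, direction down, camera adjusted p = 0.742), the fall being that of keratin Krt19, by 3.05 (SE 0.32, adjusted p = 0.00310). The 14 endothelial markers held 1 rise (0 when adjusted over the list alone; median 0.21 [0.07 to 0.37 over settings], camera adjusted p = 0.318): the angiopoietin receptor Tek rose by 4.27 (SE 1.07, adjusted p = 0.0378), a call lost without any clone other than knockout clone H (0.0964 to 0.111). Of 15 macrophage markers, 0 passed in limma under either adjustment (median 0.12 [-0.04 to 0.21 over settings], camera adjusted p = 0.401), the nearest being Cd14 (-0.75, unadjusted p = 0.00971, adjusted p = 0.0508), which passed in 5 of 15 settings: without knockout clone E (-0.93, 0.0330), with array weights (0.0414), after median centring (0.0370) or regional subtraction (0.0442), and with probe sets averaged (0.0492). The 15 neural and glial markers held 0 rises and 2 falls under either adjustment (median -0.01 [-0.81 to 0.05 over settings], camera adjusted p = 0.508). The neuronal tubulin Tubb3 was among them (-3.20, SE 0.78, adjusted p = 0.0344), a call lost without any clone other than knockout clone H (0.0620 to 0.118).

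Genes near Fhl2 on its chromosome, where DNA from the strain of the targeted cells can remain beside a knockout allele, did not move as a list. Camera looks for a shift in 1 direction, so it cannot tell whether such DNA raised some neighbours and lowered others. Of 35 measured neighbours, 3 rose and 2 fell, where 19% of all genes tested passed. The counts were 2 and 1 when adjusted over the list alone (median 0.06 [-0.01 to 0.10 over settings], camera adjusted p = 0.780). Lonrf2, a ring-finger protein, rose by 1.30 (SE 0.09, adjusted p = 0.00130), or by 0.73 with probe sets averaged, and Mitd1, of cytokinesis, fell by 0.96 (SE 0.15, adjusted p = 0.00917).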

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

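No test in this part was chosen after a result was seen: the count of probe sets outside the gene table was fixed beforehand. Signal lay in probe sets that the comparison did not use. Of 10092 probe sets without a gene name or with several symbols, 587 passed, or 5.82%, of which 270 were higher and 317 lower in knockout clones. The same fit passed 6280 of all 45037 probe sets, a larger share. What they measure was not analysed here. Groups of 3 clones were not tested for outliers, so the position of knockout clone H is given as a description.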

How the results depend on the processing

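No setting in this part was chosen after a result was seen, apart from leaving out genes of the X and Y chromosomes and subtracting the regional median, which were added once the values were known. No paired analysis was possible because the groups share only 1 clone letter. Signal over background limits low values: a reading near the lower end of the scale, in knockout clones for falls or in wild type clones for rises, makes the size of the difference inexact. Fhl2 kept its call in every alternative (-3.42 to -2.77, adjusted p = 0.00219 to 0.0203), but the alternative without probe sets open to cross-hybridization gave no value for it, since its only probe set is of that kind.

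Leaving out 1 clone gave 1661 changed genes (without wild type clone E) to 4750 (without knockout clone H), 6 to 14 called lists, 90 to 253 changed list members, and 65.1% to 81.8% of variance on the first component. The rise without knockout clone H comes with a smaller spread among the knockout clones; the cause was not tested. Counts moved to 6280 when every probe set was tested and to 1495 with a 2-fold threshold, both of which follow from how the count is made, and 0 lists were called with estimated correlations in camera. The other settings gave 2920 genes (without probe sets open to cross-hybridization) to 4926 (array weights), and 3311 after regional subtraction, of which 2842 were shared with the 3464. The share of calls that were higher in knockout clones was 47.5% in the main fit. It was 37.7% after median centring (1332 higher and 2205 lower) and 51.2% after quantile normalization (1744 higher and 1661 lower). The balance of rises and falls therefore depends on the normalization.

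The difference of Tnnt2 reversed, to 0.29, without probe sets open to cross-hybridization. In the counts that follow, a result was weakened where its call was lost and strengthened where a call was gained. A result was left where its call stayed the same, even if the size of the difference moved, as for Scara5 (7.84 to 4.12 with probe sets averaged). Among named genes, leaving out 1 clone weakened 142 results, strengthened 14 and left 696. Other settings weakened 47, strengthened 26 and left 1428, and the 47 include calls lost to the 2-fold threshold. Named genes that lost their call numbered 38 without wild type clone E, 29 without knockout clone J, 27 without wild type clone F, 24 without knockout clone E, 23 without wild type clone I and 1 without knockout clone H. Wild type clone E, whose loss cost the most calls, is also the array written with more decimals, and whether it was normalized with the others is not known. Among lists, leaving out 1 clone weakened 7 results, strengthened 9 and left 164; other settings weakened 19, strengthened 8 and left 303. Among genes chosen later, the counts were 65, 2 and 137, and 23, 2 and 333. Lists of the G1/S transition, DNA replication, mitosis, p53 targets and interferon-stimulated genes passed in 15 of 15 settings with the preset correlation, collagens and matrix in 14, integrins in 12 and SRF/MRTF targets in 5.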

Other observations

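The lists of the insulin-like growth factor axis and of MHC class I antigen presentation, the p53 regional test, the shuffled gene orders and the copy number test were chosen after the results were seen; the other tests in this part were written down before their values. The insulin-like growth factor axis, listed after Igf2, Igfbp4 and Igfbp7 were seen to change, had a median of 0.11 at percentile 90.5 of random lists, below the bound of 95. Of 18 measured members, 6 rose and 2 fell, or 44.4%; this share was not tested, because the list was written around genes that had changed, and a median does not show changes in both directions. Besides Igf2 (4.81) and Igfbp4 (2.54), Igfbp2, a binding protein, rose by 4.71 (adjusted p = 0.00177) and Igf1, the postnatal growth factor, by 4.51 (adjusted p = 0.00311), and both passed in every setting. The adaptor Irs1 rose by 1.49 (adjusted p = 0.0206), a call lost without knockout clone E (0.0570) or knockout clone J (0.0690). Pappa, a protease of these binding proteins, rose by 2.28 (adjusted p = 0.0390), a call lost in 5 of 16 settings (up to 0.123). Igfbp7 fell by 1.70 and Stc2, an inhibitor of Pappa, by 0.75 (adjusted p = 0.0458), the latter lost in several settings (up to 0.186).

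Genes of MHC class I antigen presentation, many of them induced by interferon, held changes both ways. Of 14 measured members, 2 rose and 2 fell, with a median of -0.33 at percentile 2.97 of random lists. Nlrc5, the transactivator of these genes, fell by 2.92 (adjusted p = 0.00397) and passed in every setting. B2m, the invariant chain, fell by 0.74 (adjusted p = 0.0185), a call lost without knockout clone J (0.0559), wild type clone F (0.0654) or wild type clone I (0.0589). The peptide transporter Tap2 rose by 1.45 (adjusted p = 0.00756) in every setting, and Psmb9 by 0.64 with all 6 clones.

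Whether the genotype difference exceeds that of arbitrary groups of clones cannot be told from 10 splits, since these are too few for a share under 0.05. The real split gave 3464 genes and the highest other split 0, so 1 of 10 splits reached the real count. For lists, 3 of 10 splits reached the 8 of the real one, and the highest other gave 10 (knockout clones E and J with wild type clone F against the rest). The number of called lists thus does not set the real split apart. Every other split put unequal numbers of each genotype on its sides, so part of the genotype difference remained in it. These splits therefore cannot show how many lists arbitrary groups would give.

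Of 19 p53 targets 10 rose and 1 fell, and Cdkn2a was lower in every knockout clone. Random lists take genes as independent, so percentiles among them do not measure the spread between clones. A second list of 38 p53 targets, of which 36 were measured, had a median of 0.44. This lay at percentile 100 of 10000 random lists, whose median was -0.01. Of its members 9 rose, 4 fell and 23 did not pass. Those that fell, against the direction of the list, included Epha2 (-1.43, adjusted p = 0.00251) and Tigar (-1.43, adjusted p = 0.00415). Regional shifts do not account for it: after the regional median was subtracted Cdkn1a was 3.65 (adjusted p = 9.38e-04), Cdkn2a -2.0 (adjusted p = 0.00721) and the p53 list median 0.83 (camera adjusted p = 2.72e-05 at the preset correlation; before subtraction, adjusted p = 0.326 with an estimated correlation). These values are consistent with the hypothesis that p53 is less active in the wild type clones than in the knockout clones; fibroblasts that become immortal spontaneously often lose p53 or Arf function, so this may be a property of the clones rather than an effect of FHL2. Sequencing of p53 in the clones, or a p53 response to DNA damage, could tell, and neither was analysed here.

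Hoxc4, Hoxc5, Hoxc6, Hoxc8 and Hoxc9 were lower in every knockout clone. Loss of a region that takes in most of the 10 measured genes on each side does not account for it. Their median was -0.12, from -1.06 for Tarbp2 to 0.75 for Zfp385a. Of these neighbours 2 fell, Tarbp2 and Cbx5 (-0.67, adjusted p = 0.00698), and 1 rose, Zfp385a. A median over these genes cannot exclude a shorter loss that reaches only those nearest the cluster. Loss of DNA inside the cluster remains open: Hoxc9 read 6.35 in the knockout clones, but its SD of 0.016 lay at percentile 0.4 of 500 genes of like level, so this reading could be a fixed background rather than expression. Fibroblasts of a different body position in the groups, another hypothesis, could not be told either: of 48 measured positional transcription factors 6 rose and 4 fell, or 20.8%, at percentile 74.7 of random lists (median 16.7%). Among these, Prrx2 (2.18), Twist1 (1.18), Dlx2 (1.60) and Osr1 (1.8) rose and Tbx3 fell by 2.11 in every setting, the last by 1.07 with probe sets averaged.

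Runs of neighbouring genes were shifted together. Shifted windows numbered 29, 51 and 48 of 424 for knockout clones E, H and J, and 23, 35 and 32 for wild type clones E, F and I. The sum of 218 of 2544 compares with at most 2 in 100 shuffled gene orders, so chance placement of genes does not account for them. Each clone was measured against the median of the other 5, so a shift shared by a genotype also counts. The window counts therefore do not separate shifts of single clones from shifts by genotype. In knockout clone H, 93.9% of the 229 genes from Cul2 to Tmx3 lay lower than the median of the other 5 clones (median -0.95, a factor of 0.517), against 52.2% of genes elsewhere, and in wild type clone I, 88.9% of the 316 genes from Gdi2 to Zfp131 lay higher on the same measure (median 0.50, a factor of 1.42). The actin 3' to 5' difference of clone H, 0.103, lay among those of the other clones, as did that of Gapdh, -0.045. These differences did not set the RNA of clone H apart, but they cannot exclude other faults of its array. The values go with the hypothesis of chromosome copy number changes in single clones, which was not tested on DNA. Shifts also followed genotype: on 13 of 20 chromosomes the medians of all knockout clones lay on one side of all wild type clones, where chance gives 10% for a single chromosome. The upper quartiles of whole arrays moved with genotype too (7.03 to 7.07 in knockout and 7.09 to 7.12 in wild type clones). Small differences, such as -0.11 for the 607 genes from Cdk6 to Rfc3, need therefore not be regional. The largest difference was that of Cul2 to Tmx3 itself (-0.55, 33.6% of genes lower and 1.75% higher). Measured from the mean of all 6 clones, its medians were -0.03, -0.72 and -0.05 in knockout clones E, H and J, against 0.19 to 0.38 in wild type clones. Its rank thus rests largely on clone H, and the factor of 0.517 includes part of the difference by genotype. Next came the 305 genes from Rab10os to Cdca7l (0.51, 46.6% higher and 3.28% lower), then the 550 genes from Cd99 to Noc2l (-0.36, 32.5% lower and 7.45% higher). Copy number could therefore account for part of the genotype calls, of which 2842 of 3464 remained after regional subtraction. Since that subtraction can leave part of a shift, the calls that remained are not shown to be free of copy number effects. The Xist and Y-linked readings of clone H may point to a female embryo, which was not tested.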
